A study of Mus musculus with 4 samples.

How the data were processed

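Cytoplasmic RNA of Neuro2A cells was measured on 4 mouse Affymetrix arrays, 2 of 4.5SH-depleted cells and 2 of control cells. Per the labels' protocols, dishes were transfected with antisense oligonucleotides at 30 nM, the cytoplasmic fraction was the supernatant of a detergent lysate, and biotinylated cRNA was made from 200 ng of poly(A)+ RNA. Which oligonucleotide the control cells received is not given in the sources used here. The labels call the replicates biological; whether they came from separate transfections or days is not stated, so p-values measure the spread between these samples.

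The deposited values are intensities, 1 MAS5 signal per probe set on a linear scale, as named in the submitters' processing notes. The software version, the scaling target and any filter are not given in the sources used here. The 2% trimmed means differed between the arrays (128 and 133 in the knockdown, 149 and 144 in the control), so whether the arrays had been scaled to a common target stays unknown. Medians of the signal were 17.1, 18.2, 18.0 and 18.3 in the same order. The ratio of the 3' to the 5' Gapdh control probe set was 0.833 and 0.787 in the knockdown and 0.884 and 0.861 in the control, and that of Actb 2.47 and 2.49 against 2.60 and 2.78.

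The arrays held 45101 probe sets, of which 64 were controls. Of the other 45037, 34945 carried 1 gene symbol in the annotation used, 932 several and 9160 none, and genes were named from the first kind alone. Symbols were matched by Entrez identifier to a RefSeq gene table for 34741 probe sets. Values were taken as log2(signal + 16) without further scaling. Because of the pseudocount, a fold change understates the change of dim genes. Probe sets whose mean over all 4 arrays was at or above the median were tested, which left 22519 probe sets and 11804 genes above a signal of about 16.4. Each gene was represented by its brightest tested probe set.

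Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided, 13.6 total degrees of freedom, Benjamini-Hochberg adjustment at 0.05). With 2 against 2 arrays an exact permutation test cannot give a p below 0.333, so every p rests on the variance that limma shares across genes. Fixed gene lists were tested with camera at a preset correlation of 0.01, with fry beside it, adjusted over 24 lists. Camera with an estimated correlation was an alternative. It rests on the few residual degrees of freedom of 4 arrays, so hardly any list could pass it after adjustment. Not passing it therefore says little about a list. Of the lists 23 named 497 genes, of which 466 had a probe set with 1 symbol and 411 were tested. The others, 31 without such a probe set and the rest below the filter, were not analysed here. The last list took all genes whose symbol begins with Zfp. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

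The design, the lists and the rule for named genes were set before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes with no overlap between groups, up to 4 members of each list that passed over the list alone (by p, or the 2 with the smallest p where none passed), and the control genes Gapdh, Actb, Malat1 and Neat1. A planned comparison of genes with an antisense B1 element in the 3' untranslated region was not run, because it needs transcript sequences, which were not used here.

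Alternatives were pseudocounts of 1 and 64, quantile scaling, centring on the median of all probe sets, no filter, the brightest 25%, no intensity trend, a replicate block, leaving out probe sets ending in _x_at or _s_at, the mean of all probe sets of a gene, other thresholds, and leaving out each array in turn. Centring on the median of the tested probe sets and on the 9 hybridization spike-in probe sets (spike-in scaling) was added after the data were seen. On data simulated for this comparison over 11804 genes, limma called 88 of 100 genes changed by a log2 of 1, 51 of 100 changed by 0.5, and 7 of 11604 unchanged genes. The simulation changed few genes, with random signs, independent noise and no shift between arrays. In the data 5311 genes were called, most of them lower. The simulated counts therefore do not give the number of false or missed calls here.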

Results

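Cytoplasmic RNA was profiled in Neuro2A cells, a mouse neuroblastoma line, after depletion of 4.5SH, a small noncoding RNA of rodents that is related in sequence to the B1 family of short interspersed elements. The 4 arrays fell into a 4.5SH knockdown group and a control group of 2 biological replicates each, as the labels name them. The stated aim was to find genes carrying an antisense B1 element on which 4.5SH acts. No probe set was named for 4.5SH in the annotation used, so the level of the depleted RNA itself was not analysed here. The oligonucleotide of the control cells is not given either. Effects of 4.5SH loss and other effects of the transfected oligonucleotides thus cannot be told apart in any comparison below. The trimmed mean signal per array was 128 and 133 in the knockdown and 149 and 144 in the control, and the number of arrays limits the precision of every value. Log2 profiles correlated across probe sets at 0.9914 between the knockdown arrays, 0.9911 between the control arrays and 0.9708 to 0.9733 between groups. Values after ± are standard errors of the limma fit on 2 against 2 arrays, unless marked SD.

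Depletion of 4.5SH was accompanied by a rise at 1 of 3 tested probe sets for Xist, the noncoding RNA that coats the inactive X chromosome. The log2 fold change at this probe set, the brightest, was 2.69 ± 0.17 (adjusted p = 4.19e-09, limma). It read 178 ± 18.8 in the knockdown and 13.9 ± 1.98 in the control (SD, n = 2). The other 2 tested probe sets for Xist differed by 0.22 and 0.17 and did not pass. Cross-hybridization at the brightest one thus stays open. Cdk8, a kinase of the Mediator complex, rose by 1.66 ± 0.11, from a signal of 135 ± 15.1 to 459 ± 26 (SD, n = 2). Vamp4, a membrane fusion protein of the Golgi and endosomes, rose by 1.33 ± 0.09 with both of its tested probe sets higher, and Rpe, an epimerase of the pentose phosphate pathway, rose by 1.28 ± 0.09, also with both. The 12 largest rises further held the T cell receptor kinase Zap70 (1.52), the membrane ubiquitin ligase Marchf8 (1.45), the interferon-inducible GTPase Irgm2 (1.34), the interferon-induced chaperone Rtp4 (1.28), the attractin-like gene Atrnl1 (1.28), the zinc finger gene Zfp820 (1.25), the noncoding Gm4285 (1.96) and the protein-coding 1110051M20Rik (1.38).

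The largest fall was that of Nfkbie, an inhibitor of NF-kappaB, at -3.09 ± 0.16 (adjusted p = 7.42e-10, limma), with both of its tested probe sets lower and a signal of 25.6 ± 8.98 against 336 ± 51.7 (SD, n = 2). The signalling adaptor Gab2 fell by 2.55 ± 0.17, with 2 of 3 tested probe sets lower. Malat1, a long noncoding RNA of the nucleus, fell by 2.50 ± 0.14 (adjusted p = 1.39e-09, limma) at its brightest probe set, but of its 4 tested probe sets 2 were lower and 1 was higher, by 0.93. Lin7b, a scaffold protein of cell junctions and synapses, fell by 2.09 ± 0.11 at the brightest of 4 probe sets, all lower. Hspb11, a protein of intraflagellar transport, fell by 2.40 ± 0.09, from 973 ± 24.5 to 171 ± 6.86 (SD, n = 2). Among the 12 largest falls were also genes best known from other tissues: the photoreceptor genes Sag (-2.50) and Cdhr1 (-2.39), the Fc receptor chain Fcer1g (-2.02) and the muscle gene Mybpc2 (-1.94). The neuronal catenin Ctnna2 (-1.94), the imprinted zinc finger gene Plagl1 (-2.31) and the transcription factor Tfcp2 (-2.18) completed them. All 24 genes were chosen for large changes that passed with no overlap between the groups' arrays. They kept their direction and call under every alternative that measured them, though only 7 had more than 1 tested probe set. Further probe sets below the filter, as for Zap70, Plagl1, Atrnl1 and Hspb11, represented these genes in none of the alternatives. For Zap70 such probe sets read 2.65 in the knockdown against 14.05 in the control, and 8.9 against 2.2. Sizes were less firm: the mean of all probe sets of a gene gave 1.03 for Xist, -1.21 for Gab2 and -0.60 for Malat1, and a pseudocount of 1 gave 2.98 for Gm4285 and 2.33 for Zap70. A pseudocount of 64 made 12 of the 24 changes smaller by over 1.5 times, such as Plagl1 (-1.05), Gm4285 (1.02), Zap70 (0.76), Zfp820 (0.66), Cdhr1 (-1.39) and Xist (1.63).

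**Figure D1:**
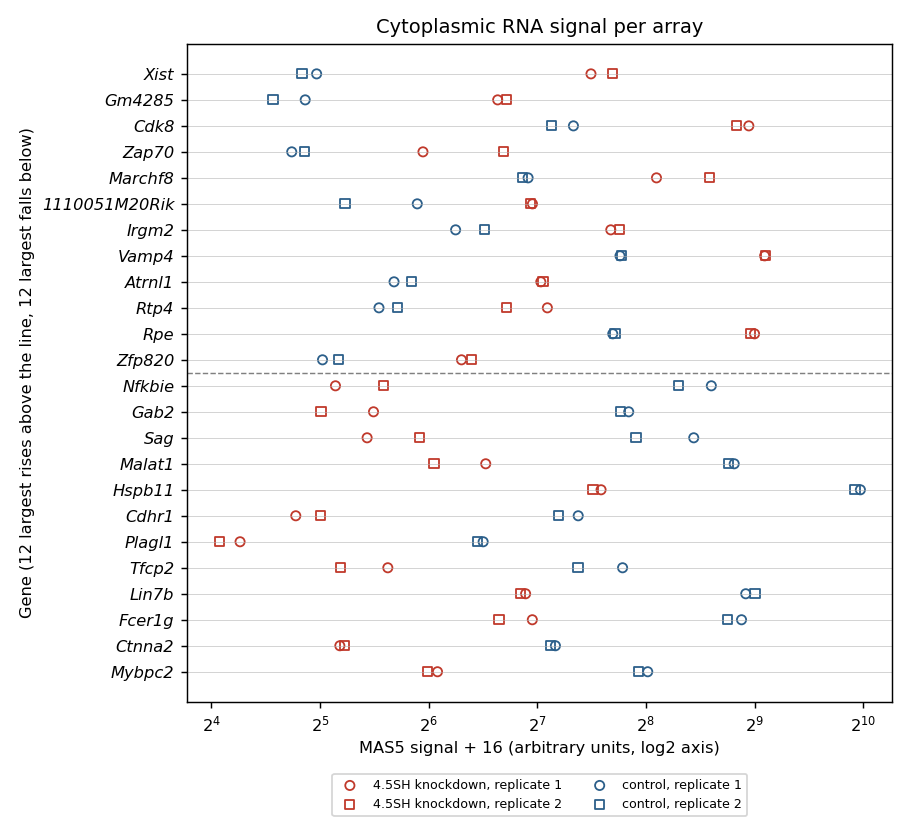
MAS5 signal plus 16 (arbitrary units, log2 axis) on each of the 4 arrays for the 12 genes with the largest rise and the 12 with the largest fall, with circles for replicate 1 and squares for replicate 2 of the 4.5SH knockdown (red) and control (blue). By the rule that chose these genes, both knockdown arrays lie on the same side of both control arrays. In Xist the signals were 164.3 and 190.9 against 15.3 and 12.5.

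At gene level 5311 of 11804 tested genes passed a limma adjusted p threshold of 0.05, of which 1156 were higher and 4155 lower in the knockdown. This split moved with the scaling of the arrays: 2092 were higher and 2665 lower with quantile scaling, 2004 and 2861 after centring on the tested probe sets, 1224 and 3824 after centring on all probe sets, and 699 and 4895 with spike-in scaling. Without knockdown replicate 2 there were 705 higher and 3537 lower genes, and 1207 higher and 4757 lower probe sets. The median log2 fold change of all tested genes was -0.16 on the deposited scale and -0.04, -0.03, -0.14 and -0.25 in the same order of scalings, so 0 lay above the typical gene on each scale. Changes of at least 2-fold were counted in 36 higher and 276 lower genes, among them Cdk8 and Nfkbie. At probe set level 8002 of 22519 passed, 2192 higher and 5810 lower, with 3816 higher and 3748 lower under quantile scaling. The groups did not overlap in 66.8% of tested probe sets. Chance gives 33.3% if no shift separates the arrays of the groups. All probe sets share the same arrays, so such a shift would also raise the share. The excess over 33.3% thus cannot tell changes in the cells from differences between the arrays.

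Genes of the interferon response, fixed as a list beforehand, were higher as a group by camera at a preset correlation (adjusted p = 0.000667) but not at an estimated correlation (adjusted p = 0.718). Of 18 measured, 7 rose, 1 fell and 10 did not pass. Adjusted over the list alone 8 rose and 2 fell. Over all genes 6 rose and 2 fell with spike-in scaling, and 12 rose and 1 fell after centring on the tested probe sets. The interferon-induced genes Oasl2 (1.08 ± 0.20), Ifit1 (1.06 ± 0.20) and Usp18 (0.75 ± 0.14) rose, while the transcription factor Irf1 fell by 0.96 ± 0.07. With a pseudocount of 64 Oasl2 was at 0.60 and Ifit1 at 0.54. The list's median was 0.32. The heat shock list was also higher (median 0.26, camera adjusted p = 0.00201, and adjusted p = 0.718 with an estimated correlation), with 7 of 12 measured genes risen, 2 fallen and 3 not passed. The counts were the same adjusted over the list alone. The chaperones Hsp90aa1 (0.66 ± 0.05), Dnaja1 (0.43 ± 0.05) and Hspa8 (0.31 ± 0.04) rose and the mitochondrial chaperonin Hspe1 fell by 0.37 ± 0.05. Without probe sets ending in _x_at or _s_at Hspa8 was at 0.65. Without the dimmer probe sets, on the brightest 25% alone, where 5 of the 18 interferon genes remained with a median of 0.147, the interferon list no longer passed (adjusted p = 0.697).

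Of 20 measured cholesterol synthesis genes 6 rose, 3 fell and 11 did not pass. These counts held when adjusted over the list alone, and over all genes 8 rose and 1 fell with quantile scaling, and 4 rose and 4 fell with spike-in scaling. Stard4, a sterol transport protein, rose by 0.98 ± 0.10, Hmgcs1, which makes the precursor of mevalonate, by 0.67 ± 0.08 and the sterol oxidase Msmo1 by 0.39 ± 0.07, while the squalene synthase Fdft1 fell by 0.49 ± 0.07. The list's median of 0.06 turned to -0.03 with spike-in scaling, and its camera test relative to other genes was upward (adjusted p = 0.00942, and adjusted p = 0.718 with an estimated correlation). The largest list took all genes named Zfp, which are zinc finger genes: of 267 measured, 54 rose, 36 fell and 177 did not pass (50 and 34 adjusted over the list alone). With quantile scaling 71 Zfp genes rose and 18 fell, whereas with spike-in scaling 36 rose and 46 fell and the median went from 0.08 to -0.01. Zfp365 (0.79 ± 0.10) and Zfp617 (0.67 ± 0.08) rose, and Zfp346 (-1.85 ± 0.12) and Zfp622 (-0.46 ± 0.05) fell. Relative to other genes the Zfp list was higher by camera (adjusted p = 6.69e-06, and adjusted p = 0.718 with an estimated correlation).

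DNA replication genes were lower as a group by camera at a preset correlation (adjusted p = 0.00787) but not at an estimated correlation (adjusted p = 0.718) or with quantile scaling (adjusted p = 0.0678). Of 33 measured, 1 rose, 23 fell and 9 did not pass. Adjusted over the list alone 3 rose and 23 fell, and over all genes 6 rose and 17 fell with quantile scaling. The helicase subunit Mcm7 (-0.53 ± 0.05), the initiation factors Mcm10 (-0.80 ± 0.07) and Cdc45 (-0.92 ± 0.09) and the G1/S cyclin Ccne1 (-0.86 ± 0.10) fell, while Ccne2, singled out after its value was seen, rose by 0.58. The mean of probe sets was -0.45 for Mcm10 and -0.61 for Cdc45, and without probe sets ending in _x_at or _s_at Ccne1 was at -0.39. The list's median was -0.31 on the deposited scale and -0.14 with quantile scaling. Among 10000 random lists matched on mean signal, 5.31% had a lower median than the deposited one.

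Lists of mRNA export and of splicing proteins were lower as groups by camera at a preset correlation (adjusted p = 0.00566 for each) but not at an estimated correlation (adjusted p = 0.718 and 0.723). Of 21 measured mRNA export genes 16 fell, 1 rose and 4 did not pass. Counts adjusted over the list alone were equal, and over all genes 12 fell and 3 rose with quantile scaling. Thoc6, a subunit of the export complex THO, fell by 0.97 ± 0.08, the nuclear poly(A)-binding protein Pabpn1 by 0.63 ± 0.05 and the export factor Rae1 by 0.56 ± 0.07. The exception was the nuclear pore protein Nup153 (0.39), named after its value was seen. Of 27 SR and splicing proteins 18 fell, 2 rose and 7 did not pass. The counts adjusted over the list alone were 18 lower and 3 higher, and over all genes 15 fell and 4 rose with quantile scaling. Hnrnpa1 (-0.66 ± 0.06), Srsf4 (-0.64 ± 0.06) and Srsf2 (-0.72 ± 0.05) were among those lower. Of 4 tested probe sets for Srsf2 2 were lower and 2 did not pass. Their mean was -0.38, and without those ending in _x_at or _s_at, which left a dim one, the value was -0.06 and did not pass. Likewise Pabpn1 was lower at 2 of 4 tested probe sets, with a mean of -0.22. Medians were -0.405 for export and -0.32 for splicing, and -0.264 and -0.155 with quantile scaling. Taking the mean of all probe sets of a gene ended both calls (adjusted p = 0.149 and 0.236), as did a fit without the intensity trend (0.0630 and 0.0861) and the brightest 25% alone (0.0582 for each). The same 3 settings ended that of DNA replication (0.0867, 0.0730 and 0.0582).

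Of 23 measured genes of nuclear RNA surveillance 15 fell, 3 rose and 5 did not pass. Adjusted over the list alone 16 fell and 4 rose, and over all genes 11 fell and 4 rose with quantile scaling. The exosome subunits Exosc2 (-0.82 ± 0.06) and Exosc10 (-0.70 ± 0.07) and their helicase Mtrex (-0.69 ± 0.07) were lower. With a median of -0.35, or -0.17 with quantile scaling, the list itself did not pass camera (adjusted p = 0.118, and adjusted p = 0.745 with an estimated correlation). It passed without the filter on dim probe sets (0.0122) and without probe sets ending in _x_at or _s_at (0.0408).

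**Figure D2:**
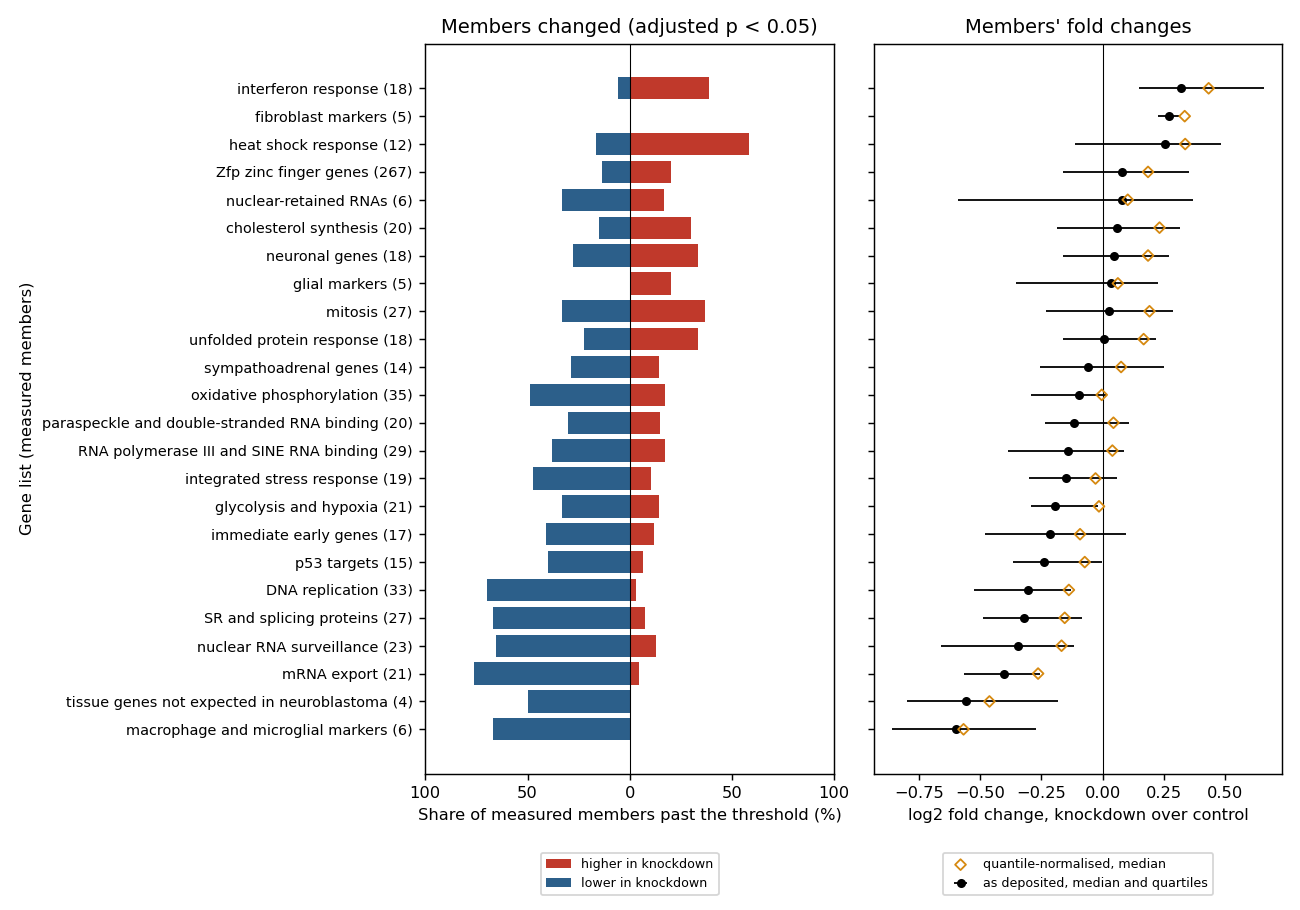
For each gene list, with its number of measured members in brackets, the left panel shows the percentage of members higher (red, right) or lower (blue, left) in the 4.5SH knockdown past a limma adjusted p of 0.05, and the right panel the median log2 fold change with quartiles on the deposited scale (black) and the median with quantile scaling (orange). The interferon median lies at 0.32 and that of mRNA export at -0.405, while lists near 0, such as cholesterol synthesis at 0.06, turn negative with spike-in scaling.

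Mitotic genes moved in both directions: of 27 measured, 10 rose, 9 fell and 8 did not pass. The counts were the same adjusted over the list alone, and over all genes 13 rose and 6 fell with quantile scaling, and 5 rose and 11 fell with spike-in scaling. The kinetochore protein Cenpf (0.96 ± 0.09) and cyclin A, Ccna2 (0.59 ± 0.09), rose, and Birc5, the survivin gene (-1.13 ± 0.07), and the phosphatase Cdc25c (-0.94 ± 0.10) fell. Neuronal genes were as mixed, with 6 of 18 risen, 5 fallen and 7 not passed. The counts adjusted over the list alone were 8 higher and 5 lower, and over all genes 10 rose and 3 fell with quantile scaling and 3 rose and 5 fell with spike-in scaling. The synaptic vesicle sensor Syt1 (1.03 ± 0.12) and the microtubule protein Map2 (0.61 ± 0.11) rose and Mapt, the tau gene (-0.87 ± 0.12), fell. The mean of probe sets for Syt1 was 0.65. The adhesion molecule Ncam1 was at -0.55 ± 0.09 by its brightest probe set and at 0.12, not passing, as the mean of its probe sets. In the unfolded protein response list 6 of 18 rose, 4 fell and 8 did not pass. These counts held when adjusted over the list alone, and over all genes 9 rose and 3 fell with quantile scaling, and 4 rose and 5 fell with spike-in scaling. The chaperones Dnajb9 (0.74 ± 0.09), Hsp90b1 (0.55 ± 0.07) and Canx (0.51 ± 0.06) were higher and the disulfide isomerase Pdia6 (-0.65 ± 0.10) lower. By camera the adjusted p was 0.132 for mitosis, 0.0723 for neuronal genes and 0.0517 for the unfolded protein response (adjusted p = 0.745, 0.723 and 0.745 with an estimated correlation). With quantile scaling all 3 passed, in the upward direction (0.0283, 0.0211 and 0.0211). Neuronal genes also passed after centring on the tested probe sets (0.0294) and without probe sets ending in _x_at or _s_at (0.0476). The unfolded protein response passed in these settings too (0.0314 and 0.0408), after centring on all probe sets (0.0498), on the brightest 25% (0.0257), with a replicate block (0.0298) and without control replicate 1 (0.0104).

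Among p53 targets 1 of 15 rose, 6 fell and 8 did not pass. Counts adjusted over the list alone were equal, and over all genes 2 rose and 4 fell with quantile scaling. Cyclin G1, Ccng1, rose by 1.06 ± 0.12, whereas the cell cycle inhibitor Cdkn1a (-0.38 ± 0.06), the nuclease Aen (-0.55 ± 0.12) and the pro-apoptotic Bbc3 (-0.54 ± 0.12) fell. With quantile scaling Ccng1 was at 1.22, Cdkn1a at -0.22, Aen at -0.37 and Bbc3 at -0.40. Immediate early genes fell in 7 of 17 cases and rose in 2, with 8 not passed. Adjusted over the list alone 9 fell and 2 rose, and over all genes 5 fell and 3 rose with quantile scaling. Egr1 fell by 1.16 ± 0.09, Ier2 by 0.93 ± 0.07 and Junb by 0.93 ± 0.08, while Klf4 rose by 0.80 ± 0.10. In the integrated stress response 9 of 19 fell, 2 rose and 8 did not pass. The counts were the same adjusted over the list alone, and over all genes 5 fell and 6 rose with quantile scaling. The transcription factor Cebpb (-0.65 ± 0.07) and the amino acid transporter chain Slc3a2 (-0.39 ± 0.05) were lower, and Ddit3, which encodes CHOP, was at -0.56 ± 0.05 by its brightest probe set but at 0.14 as the mean of its probe sets. None of these lists passed camera (adjusted p = 0.903, 0.643 and 0.643, and 0.965, 0.965 and 0.745 with an estimated correlation).

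In the list of RNA polymerase III and SINE RNA-binding proteins, the machinery that makes and binds RNAs such as 4.5SH, 5 of 29 rose, 11 fell and 13 did not pass. These counts held when adjusted over the list alone, and over all genes 7 rose and 7 fell with quantile scaling, and 2 rose and 12 fell with spike-in scaling. The polymerase III repressor Maf1 (-0.58 ± 0.06), the subunit Polr3c (-0.67 ± 0.08), the factor Gtf3c1 (-0.64 ± 0.10) and the Alu and B1 RNA-binding protein Srp14 (-0.33 ± 0.05) fell. The mean of probe sets was -0.36 for Maf1, -0.42 for Polr3c and -0.70 for Srp14, whose other 3 tested probe sets fell by more. Of 20 paraspeckle and double-stranded RNA-binding proteins 3 rose, 6 fell and 11 did not pass. The counts adjusted over the list alone were 4 higher and 8 lower, and over all genes 7 rose and 4 fell with quantile scaling and 1 rose and 10 fell with spike-in scaling. The helicase Dhx9 (-0.79 ± 0.06) and the RNA-binding protein Ewsr1 (-0.55 ± 0.05) were lower. Both medians (-0.14 and -0.12) turned positive with quantile scaling, at 0.04 each, and neither list passed camera (adjusted p = 0.921 for both, and 0.966 with an estimated correlation). Of 6 measured nuclear-retained RNAs 1 rose (Xist), 2 fell (Malat1 and Neat1) and 3 did not pass. The fall of Neat1, the scaffold RNA of paraspeckles (-0.72 ± 0.23, adjusted p = 0.0163, limma), was lost in 5 of 15 alternatives. These were the mean of its probe sets (-0.27, adjusted p = 0.386), centring on the tested probe sets (-0.59, 0.0566), no filter (0.0673), and the fits without knockdown replicate 2 (-0.51, 0.133) or control replicate 1 (-0.67, 0.0694). Its size was -1.14 with a pseudocount of 1 and -0.34 with 64. The list gave the same counts adjusted over the list alone and a camera adjusted p of 0.5 (0.745 with an estimated correlation), with a median of 0.08 that was -0.01 with spike-in scaling.

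Oxidative phosphorylation genes fell in 17 of 35 cases and rose in 6, with 12 not passed. Counts adjusted over the list alone were equal, and over all genes 10 fell and 9 rose after centring on the tested probe sets, and 18 fell and 2 rose with spike-in scaling. The complex I subunits Ndufb8 (-0.85 ± 0.05), Ndufs3 (-0.61 ± 0.06), Ndufa5 (-0.57 ± 0.05) and Ndufb3 (-0.54 ± 0.06) were lower. As the mean of their probe sets Ndufb8 was at -0.29, its other tested probe set not passing (0.256), and Ndufa5 at -0.94. The list's median of -0.10 turned to 0.04 after centring on the tested probe sets (camera adjusted p = 0.339, and 0.723 with an estimated correlation). In glycolysis and hypoxia 7 of 21 fell, 3 rose and 11 did not pass. The counts were the same adjusted over the list alone, and over all genes 2 fell and 4 rose with quantile scaling, and 12 fell and 0 rose with spike-in scaling. The mTOR inhibitor Ddit4 was lower, at -0.40 ± 0.06, and at -0.22 with quantile scaling. The list did not pass (camera adjusted p = 0.965, and 0.966 with an estimated correlation). Of 14 sympathoadrenal genes 2 rose, 4 fell and 8 did not pass. These counts held when adjusted over the list alone, and over all genes 3 rose and 2 fell with quantile scaling. The receptor kinase Alk (-1.46 ± 0.18) and the transcription factor Gata2 (-0.45 ± 0.07) fell and the granule protein Chgb (0.33 ± 0.07) rose. With a pseudocount of 64 Alk was at -0.89. The other tested probe set for Gata2 did not pass (0.00679), and the mean of both was -0.22. The list's median of -0.06 turned to 0.08 with quantile scaling, and camera gave an adjusted p of 0.623 (0.745 with an estimated correlation).

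Markers of other cell types were mostly dim. Of 6 measured macrophage and microglial markers 4 fell and 2 did not pass, the same adjusted over the list alone: Fcer1g (-2.02 ± 0.12), the lysosomal Cd68 (-0.94 ± 0.09), and at control signals of 31.9 and 26.9 Tyrobp (-0.58 ± 0.23) and Lyz2 (-0.62 ± 0.25), whose calls (adjusted p = 0.0455 and 0.0495, limma) were lost with quantile scaling (0.0636 for both). Over all alternatives the call of Tyrobp was lost in 8 and that of Lyz2 in 10 of 15, including each fit with 1 array left out (adjusted p from 0.0901 to 0.142 and from 0.0678 to 0.21). With a pseudocount of 64 they were at -0.26 each, and with 1 at -0.96 and -1.11. Of 5 glial markers the transcription factor Sox10 rose (0.76 ± 0.25), a call lost without knockdown replicate 1 (0.70, adjusted p = 0.0921), with 0.31 and 1.43 at pseudocounts of 64 and 1, and 4 did not pass. None of 5 fibroblast markers passed limma, with Pdgfra at 0.44 ± 0.21 (unadjusted p = 0.0547, the smallest, and adjusted p = 0.105) and Col6a1 at 0.31 ± 0.20, although Pdgfra passed without the intensity trend (adjusted p = 0.0394) and after centring on the tested probe sets (0.0435). Of 4 genes of unrelated tissues 2 fell and 2 did not pass, the pancreatic elastase Cela1 (-0.72 ± 0.06, control signal 2131) and the apolipoprotein Apoa1 (-1.06 ± 0.17, and -0.61 without probe sets ending in _x_at or _s_at). Adjusted over the list alone these 3 lists kept their counts, and camera gave an adjusted p of 0.138 for macrophage, 0.387 for glial, 0.132 for fibroblast and 0.439 for unrelated tissue genes (0.718, 0.723, 0.718 and 0.745 with an estimated correlation). The macrophage list passed downward with spike-in scaling (0.0234), with a replicate block (0.0298) and without control replicate 1 (0.0267).

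Of the 24 lists 7 passed camera with a preset correlation and 0 with an estimated correlation, where 1, the interferon response, had an unadjusted p under 0.05 (0.0488). fry tests whether a list's genes move on balance one way from 0, not relative to other genes, on a scale where the median tested gene was at -0.16. It gave an adjusted p of 0.0147 for the interferon response, 0.0458 for heat shock, 0.0269 for DNA replication, 0.0458 for mRNA export, 0.0693 for splicing, 0.0721 for cholesterol synthesis and 0.190 for Zfp genes. Among the lists that did not pass camera, fry passed in the downward direction for macrophage markers (0.00102, the smallest), oxidative phosphorylation (0.0269), the integrated stress response (0.0458) and nuclear RNA surveillance (0.0458), and not for the other 13. The medians of oxidative phosphorylation (-0.10) and of the integrated stress response (-0.15) lay above that of all tested genes. The control gene Actb was not called at its brightest probe set on the deposited scale (0.07 ± 0.05, adjusted p = 0.248, limma). It passed limma with quantile scaling (0.13, adjusted p = 0.0199) and after centring on the tested probe sets (0.20, 0.00792). Without control replicate 1 it was at 0.12, and with spike-in scaling at -0.02. Its other tested probe set was at -0.09 and did not pass, while quality-control probe sets for beta-actin were higher, by 0.253, 0.368 and 0.384. The standard error thus leaves out the spread between probe sets of 1 gene. Gapdh was measured by 3 quality-control probe sets, whose log2 differences between groups were -0.06, 0.05 and 0.0030.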

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

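The tests in this part were all chosen after the results were seen. Some control probe sets that entered no comparison were higher on both knockdown arrays than on both control arrays, with no test. The beta-actin control probe sets differed by 0.253 (3' end, mean signal 8260 against 6942), 0.368 (5' end, 3334 against 2592) and 0.384 (middle, 4033 against 3098) on the log2 scale. A control probe set for the murine B2 element was higher by 0.270 (2175 against 1800), while a brighter one for B2 was at -0.0233 (11140 against 11340) and that for B1 at 0.11 (11390 against 10550). That for the 3' end of the transferrin receptor was higher by 0.417 (69.1 against 47.6). The control probe sets for 18S ribosomal RNA went the other way, at -0.363 (3'), -0.797 (middle) and -1.03 (5'). Probe sets for the hybridization control Cre, an added RNA, were also higher, by 0.211, 0.234, 0.0929 and 0.107. Differences of such a size, as at B2 and the 3' end of beta-actin, thus cannot be read as changes in the cells.

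Most called genes were lower in the knockdown. A single scale factor per array would shift the hybridization spike-ins as it shifts the median gene. Yet 7 of 9 spike-in probe sets were higher, with a mean shift of 0.09 (SD 0.087) against a median of -0.164 over tested genes. These probe sets are repeated readings of the added RNAs bioB, bioC, bioD and Cre, so their number overstates the precision. Those for bioC were lower, at -0.0391 and -0.0315. Even the lowest lay above the median gene, which argues against a single scale factor. A difference in overall level could not account for the number of calls either, since centring on the tested probe sets left 4865 called genes against 5311. What stays open is how many genes fell: the share of lower genes among those called ranged from 56.0% to 87.5% over the other scalings. Although cRNA was made from 200 ng of poly(A)+ RNA for every array, the amount of cRNA hybridized is not known. With equal input, the signals give each gene's part of the labelled RNA. A fall of most RNAs per cell thus cannot be read from these arrays. Less labelled RNA on the knockdown arrays and a lower part for most tested genes cannot be told apart.

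Xist was higher and Malat1 lower in the knockdown. More nuclear RNA in the cytoplasmic fraction of 1 group would move nuclear-retained RNAs the same way. Xist and Malat1 lay 5.19 ± 0.22 (SE) apart on the log2 scale with opposite signs, each at its brightest probe set. The signs were known when the pattern was named, so this is no independent test. If both probe sets read their own RNA, such a difference cannot account for both together. As the mean of probe sets Xist was at 1.03 and Malat1 at -0.60. Of 4 tested probe sets for Malat1 2 were lower and 1 was higher (0.93). For 1 of the RNAs alone, more nuclear RNA in 1 group stays open. Of the 4 other nuclear-retained RNAs tested 1 (Neat1) was lower, a call lost in 5 of 15 alternatives, and 3 did not pass. For Xist, cross-hybridization of a single probe set stays open: 1 of its 3 tested probe sets was higher, and the other 2 read at most 36.5 on any array, near the filter bound of 16.4. A response of these RNAs to 4.5SH depletion is a hypothesis that was not tested.

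Of 6 measured macrophage and microglial markers 4 were lower in the knockdown, and 2 with quantile scaling. Macrophage RNA in the control samples alone would lower the other markers together with Fcer1g. Of the 5 others tested 3 fell (Cd68, Tyrobp and Lyz2) and 2 did not pass (Cd14 and Csf1r). The call of Tyrobp was lost in 8 and that of Lyz2 in 10 of 15 alternatives, and the remaining 6 markers read at most 9.3 in the control mean, under the filter bound of 16.4. Signals of different probe sets do not give a common level, so macrophage RNA in the controls and lower levels of these RNAs in the depleted cells cannot be told apart. No biological explanation was tested.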

How the results depend on the processing

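The scalings on the tested probe sets and on the spike-ins, with their tests, were chosen after the results were seen. The 24 genes with the largest changes kept direction and call in all 365 alternative values, but they were chosen for size and call in these data. Only 7 of them had more than 1 tested probe set, so for the rest the mean of probe sets repeats the main value. Of the 107 called named genes 94 kept direction and call throughout. Counts moved more, and the cause was not tested unless it is named. Quantile scaling gave 3816 probe sets higher and 3748 lower, and 2092 genes higher and 2665 lower; centring on the tested probe sets gave 3788 probe sets and 2004 genes higher, spike-in scaling 1382 and 699. Of the genes called on the deposited scale, 3815, 4017 and 4849 were called in the same direction. Without the filter on dim probe sets 5286 probe sets passed (1241 higher), more being tested; without the intensity trend 5223 did (1379 higher, 3844 lower). A fold of at least 1.5 with no overlap, without a test, took 3306 probe sets. The lists past the threshold fell from 7 to 4 with the brightest 25%, without the trend and with the mean of probe sets, and to 0 with an estimated correlation. Leaving out 1 array gave 1207 to 1982 probe sets and 705 to 1171 genes higher, lowest without knockdown replicate 2; the lone array left in a group is assumed to vary like the other group's.

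Signs turned as follows. The mean of all probe sets gave 0.14 for Ddit3, 0.12 for Ncam1 and -0.013 for Actb, and spike-in scaling -0.023 for Actb. Some lists that passed camera in no setting turned in their direction relative to other genes; their median log2 fold changes there were, for the integrated stress response, -0.029 (quantile), -0.0392 (mean of probe sets) and -0.0154 (tested probe sets). For paraspeckle proteins they were -0.118 (no filter), -0.122 (mean of probe sets), -0.208 (spike-ins) and -0.099 (without control replicate 2). For polymerase III they were -0.14 (no filter) and -0.152 (no _x_at or _s_at); for glycolysis -0.18 (no filter), -0.195 (no _x_at or _s_at) and -0.156 (without knockdown replicate 1). For p53 targets they were -0.24 (brightest 25%), -0.216 (no _x_at or _s_at), -0.0395 (mean of probe sets), -0.329 (spike-ins), -0.212 (without control replicate 1) and -0.265 (without control replicate 2), and for oxidative phosphorylation 0.0361 (tested probe sets). Over all 4 fits with 1 array left out, whether or not the direction turned, the medians ranged from -0.133 to -0.0721 for paraspeckle proteins, from -0.261 to -0.155 for glycolysis and from -0.301 to -0.199 for p53 targets.

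Arrays with the same replicate number did not deviate together (correlation 0.0017, and 0.027 in the brightest 25%), and the numbers do not pair the samples. The fit with a replicate block called 8523 probe sets (2393 higher, 6130 lower), 5393 genes and 9 lists, which added the unfolded protein response and macrophage markers (adjusted p = 0.0298 for each); under it the direction of paraspeckle proteins (-0.118) and p53 targets (-0.239) relative to other genes turned. The comparison by antisense B1 elements, with its alternatives, was not run. Signal over background limits the rest: among probe sets in the dimmest eighth of those tested 2.84% were higher and 3.62% lower, in the brightest 14.9% and 47.0%. Counts of fallen genes in bright lists, such as 17 of 35 in oxidative phosphorylation, are to be read beside that share.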

Other observations

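The symbol families in this part were chosen and tested after the results were seen, as were the genes named. Among all 11804 tested genes 4155 fell and the median log2 fold change was -0.164. Of 76 families, Polr, Nup, Mrps and Mrpl had the smallest camera p among those lower than other genes; Polr and Nup share members with the fixed lists of RNA polymerase III and mRNA export. Of 25 RNA polymerase subunits and related genes named Polr, 17 fell and 0 rose (median log2 fold change -0.33), and of 18 nucleoporins named Nup 13 fell and 2 rose (-0.46). Of 29 small subunit proteins of the mitochondrial ribosome, named Mrps, 16 fell and 0 rose (-0.24), and of the 47 large subunit proteins, named Mrpl, 24 fell and 1 rose (-0.20). None of these 4 passed camera against the other genes over 76 families (adjusted p = 0.0633, 0.0693, 0.0835 and 0.368, and 0.981 for each with an estimated correlation).

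Arih2, a ubiquitin ligase, rose at all 4 of its tested probe sets, with a log2 fold change of 1.23 ± 0.07 (SE) at the brightest and a signal of 2384 ± 298 against 1003 ± 14.8 (SD, n = 2). Zmynd11, a reader of histone methylation, rose at all 3, by 1.07 ± 0.09 (SE) at the brightest. Such accord was not universal: of 1325 genes with at least 2 changed probe sets, 96 (7.25%) had some higher and some lower.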
